A study of Homo sapiens with 8 samples.

How the data were processed

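MicroRNA (miRNA) was measured on human high-density lipoprotein (HDL), the plasma lipoprotein whose main protein is apolipoprotein A-I, before and after incubation with cultured human endothelial cells. Per the labels' protocols, HDL from human plasma was prepared by density-gradient ultracentrifugation and captured with anti-apolipoprotein A-I columns. The treatment protocol names human coronary artery endothelial cells, incubated with native HDL at 1 mg/ml of protein for 16 to 24 h, and the growth protocol also describes umbilical vein endothelial cells. RNA from the captured HDL was reverse transcribed with a multiplexed primer pool, preamplified and run on 2 TaqMan Low-Density Array cards, pools A and B, on a real-time PCR instrument. The sample titles give 4 biological replicates before incubation (pre) and 4 after it (post). They do not say which replicates share a plasma donor, so p-values measure the spread between these samples.

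The authors deposited 1 file per sample with a linear relative quantity for each assay, that is, a ratio to a reference, in a column whose header is the abbreviation RQV. The reference or calibrator, the threshold-cycle (Ct) cutoff, the rule for missing wells and any normalization between the cards are not given in the sources used here. Each file lists 750 assays under 740 names, since 10 names are listed 2 times. The 2 assays listed as miR-378 were kept apart as listing 1 and listing 2. A number sign after a name marks the less abundant strand, as in miR-126#. An assay given as na was treated as not detected. Ct values, control RNAs and card names were not used here, and the number of molecules behind a value is unknown. No interval or detection floor that needs such a depth is given.

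Relative quantities were taken to the log2 scale with no pseudocount and no further normalization, so that 1 log2 unit stands for 1 PCR cycle at perfect doubling. Undetected values were left missing. Assays detected in at least 3 of the 4 samples of each group were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with pre and post as the only term. An adjusted p is a Benjamini-Hochberg value over the 27 assays tested, and the threshold was 0.05. Values are given as mean ± SD of the log2 relative quantity over the samples in which the assay was detected. The number of detected assays and the mean level of the 16 assays detected in all 8 samples were compared with exact two-sided permutation tests over the 70 ways to choose 4 of 8 samples, which cannot go below p = 0.0286. Detection of single assays was compared with Fisher's exact test, adjusted over the 149 assays detected in any sample. Python 3.11.15 with scipy 1.17.1 was used for these. The limma code was tested on simulated data with the missing values, means and median residual SD of these samples. With 5 of 27 assays lowered by 2 log2 units, 6.8% of the changed assays were called. The share was 57.2% for a fall of 4 log2 units and 97.0% for a fall of 6. Every simulated assay had the same spread, drawn independently of the others. The residual SDs of the data ran from 0.56 to 7.19, so these shares do not hold for assays with a larger spread or for shifts that assays share. An equal spread also lets eBayes pool variances more than in the data. The shares may therefore be too high even for assays of median spread.

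Before the data were examined, the groups, the tests, most of the alternatives, 16 lists of assays and the rule for named assays were fixed. The rule names every assay past the threshold, then the assays with the smallest unadjusted p until 20 are named, miR-223, assays detected in all samples of one group and none of the other, up to 4 tested members of each list, the 10 assays with the highest mean in each group, and the control RNAs. The lists covered cell types that could give RNA to HDL (endothelium, leukocytes and platelets, red blood cells, liver, heart and skeletal muscle, smooth muscle, epithelium, neurons), clusters and families (a placental cluster, the miR-17 cluster and its paralogous clusters, let-7, miR-30, an imprinted cluster), miRNAs that earlier work measured on HDL, regulators of endothelial inflammation, and control RNAs. miR-223 was put on 3 lists with the knowledge that the study followed it. The planned set test (camera in limma) needed 3 members detected in all samples, and no list had them. The number of list members detected per sample was tested in its place, for the 12 lists with at least 3 detected members, a choice made after seeing the data. Names of 144 of the 149 detected assays matched a small RNA gene in the RefSeq table of assembly GRCh38.p14, which was used for names only because the files name no genome build.

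Alternatives were the median of the always-detected assays as reference, quantile normalization, only assays detected in all samples, eBayes with trend and robust options, a replicate block and leaving out each sample in turn. Alternatives added after seeing the data were the mean of the always-detected assays as reference, undetected values set to the lowest value of the sample, removal of values over 1000, separate scaling of 2 classes of assays (offset classes) that differ in the fractional part of their log2 values, and a rank test. The plan also named 2 other Ct cutoffs, U6 as reference and scaling per labelled card. These were not run, because they need Ct values, U6 and card names, which were not used here.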

Results

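The study compared the miRNA content of HDL before and after incubation with endothelial cells. Of the 750 assays listed for each sample, 149 were detected in at least 1 of the 8 samples and 16 in all 8. The 4 pre samples held 68, 43, 44 and 82 detected assays and the 4 post samples held 45, 44, 55 and 51. Of the 149 assays, 66 were detected in a single sample each. Within each sample the log2 values were spaced at nearly whole cycles. Over all samples, 99.1% of values lay within 0.15 cycles of the sample's own grid, against 30.0% for evenly spread values. A few assays lay far above the rest. There were 33 values over 1000 in 11 assays, and the highest single values were those of miR-520D-3P, miR-517a and miR-29a, at 21.63, 21.40 and 20.17 on the log2 scale.

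**Figure D1:**
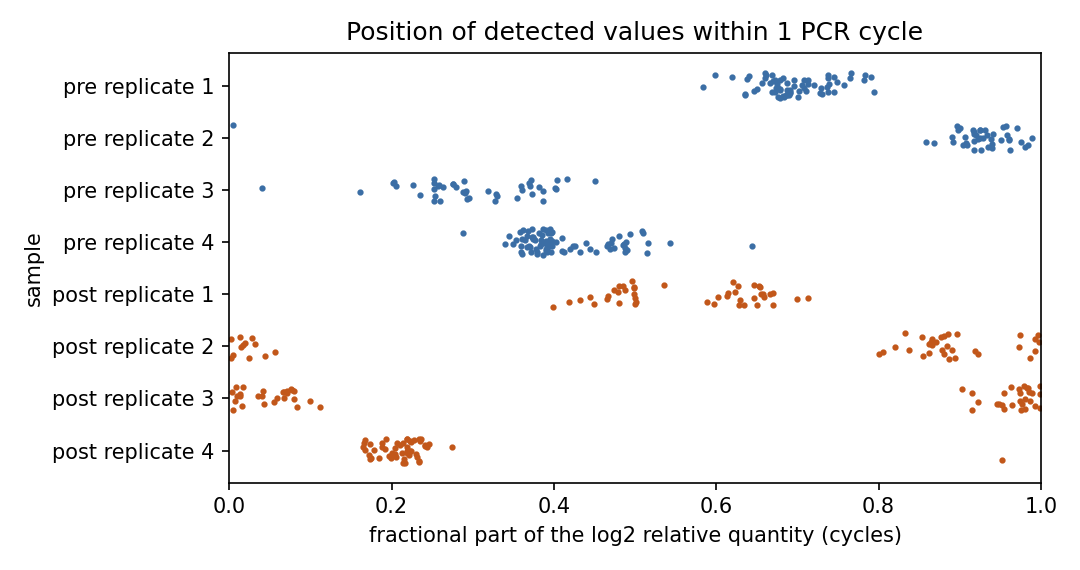
Fractional part of each detected log2 relative quantity (x axis, in PCR cycles) for the 4 pre samples in blue and the 4 post samples in orange, 1 point per detected assay with vertical jitter. Values of a sample gather at 1 position or at 2 close positions, and 99.1% of all values lie within 0.15 cycles of the sample's own position, which may wrap from 1 to 0.

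The first comparison asked whether HDL carried fewer or more measurable miRNAs after the incubation. Pre samples held 59.2 ± 19.1 detected assays (SD, n = 4) and post samples 48.8 ± 5.19 (SD, n = 4). The post minus pre difference of -10.5 assays lay within the spread between samples (exact two-sided permutation test, p = 0.429, and 0.429 adjusted over the 2 comparisons of this kind). It was -2.92 assays without pre replicate 4, -15.9 without pre replicate 2 and -7.58 without pre replicate 1. In any pre sample 122 assays were detected, in any post sample 95, and 68 in both groups. The mean log2 level of the 16 always-detected assays was 0.66 ± 0.46 (SD, n = 4) in pre and 0.01 ± 1.19 (SD, n = 4) in post samples. This shift of -0.65 log2 units was also within the spread (exact permutation p = 0.400, adjusted 0.429). It was -0.17 without post replicate 2, -1.09 without post replicate 1 and -0.43 with the median in place of the mean (exact permutation p = 0.686). One of the 16 assays, miR-520D-3P, was at 0.64 in pre replicate 1 and at 20.45 to 21.47 in the other pre samples. The pre mean, its SD and the shift therefore depend in part on that single value.

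The second comparison asked which miRNAs differed in level between HDL taken before and after contact with the cells. The lowest p belonged to miR-223, a myeloid and platelet miRNA known to be carried by HDL. Its log2 level was 3.34 ± 1.03 in pre (SD, n = 4) and -0.43 ± 1.71 in post samples (SD, n = 3), a difference of -3.77 ± 1.23 (SE), or 13.6-fold lower on average. It was not detected in post replicate 2, and the highest of its 3 detected post values, 1.5, lay below the lowest pre value of 2.29. The limma interval of the difference ran from -6.50 to -1.04 (95%). Unadjusted p was 0.0115, but the adjusted p over all 27 tested assays was 0.312, so miR-223 did not pass the threshold. Among the lists fixed beforehand it passed when adjusted over the list alone, at limma adjusted p = 0.0231 for leukocyte and platelet miRNAs (2 tested), 0.0346 for miRNAs measured earlier on HDL (3 tested) and 0.0462 for regulators of endothelial inflammation (4 tested). This adjustment was made for the main fit only. With the replicate block the unadjusted limma p of miR-223 was 0.0311, too high to pass over any of these 3 lists. That fit pooled the variance over assays. The SE of miR-223 was 1.77, as for miR-126, with residual SDs of 0.77 and 2.87. Its p with the block therefore does not reflect the spread of miR-223 itself. The lists were given miR-223 with the study in mind and are not independent evidence.

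No tested assay passed limma's adjusted p of 0.05 in either direction, and 2 had an unadjusted p under 0.05, miR-223 and miR-106b, both with a lower post mean. The level of miR-106b, a member of a cluster related to that of miR-17, was -0.43 ± 1.84 in pre (SD, n = 4) and -3.87 ± 2.00 in post samples (SD, n = 4), a difference of -3.44 ± 1.33 (SE). Its unadjusted p was 0.0248 and its limma adjusted p 0.335. The count of 2 was 4 without post replicate 1, 1 without pre replicate 1, pre replicate 3, post replicate 2 or post replicate 3, and 0 without post replicate 4. It was 6, over 43 assays, with undetected values set to the lowest value of the sample. The mean was lower in post samples for 23 of the 27 tested assays and higher for 4, with a median difference of -1.07 log2 units. When samples were scaled to the mean of the always-detected assays the median was -0.51 with 18 of 27 lower, and without pre replicate 1 it was -0.41 with 18 of 27 lower. After quantile normalization 8 of 16 were lower. The median residual SD was 1.74 log2 units.

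**Figure D2:**
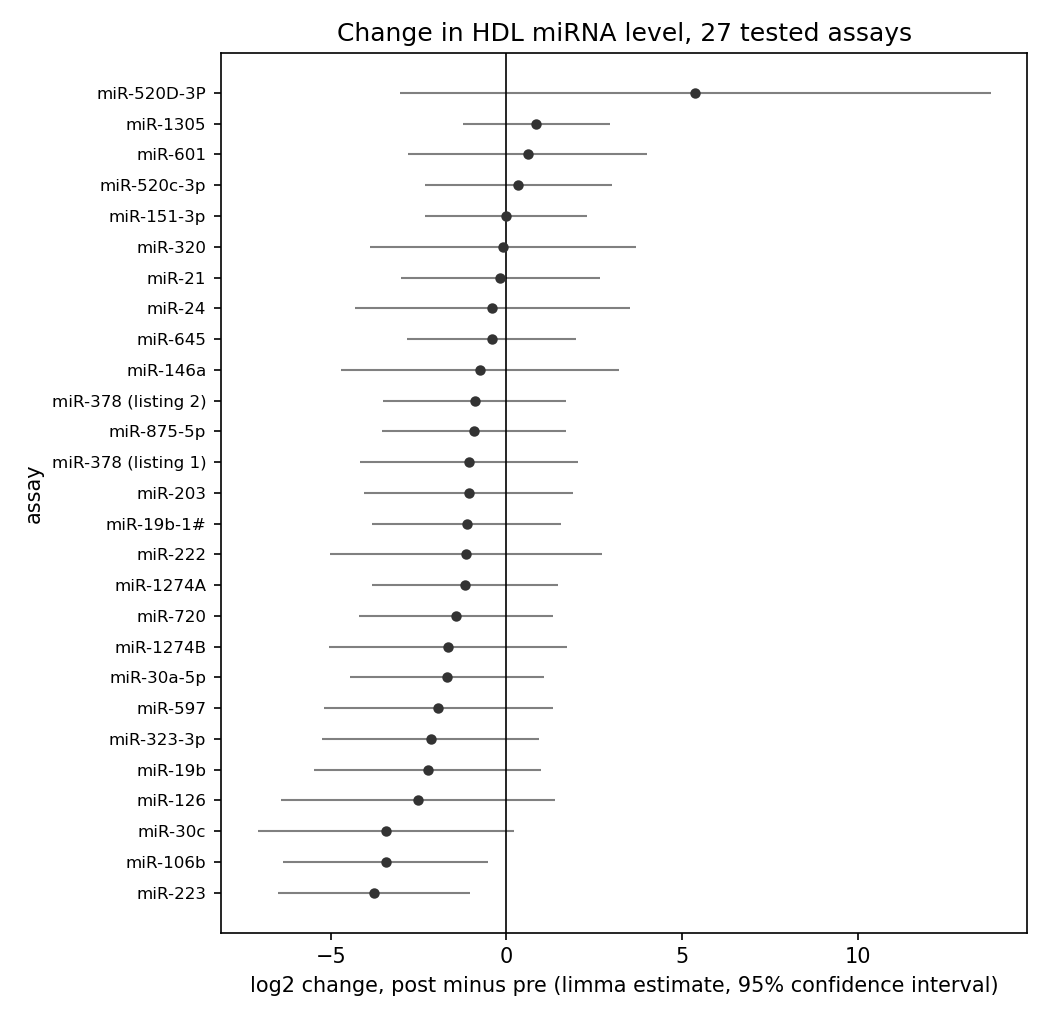
Difference in log2 relative quantity, post minus pre (x axis), for the 27 tested assays (y axis). Points are limma estimates and lines their 95% confidence intervals; the intervals of miR-223 and miR-106b alone exclude 0, before adjustment for 27 tests.

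The other named assays did not pass the threshold either. Lower post means were measured for miR-30c (-3.44 ± 1.64 SE), miR-126 (-2.52 ± 1.75), miR-19b (-2.24 ± 1.43), miR-323-3p (-2.16 ± 1.41), miR-597 (-1.94 ± 1.49), miR-30a-5p (-1.70 ± 1.26), miR-1274B (-1.66 ± 1.54), miR-720 (-1.42 ± 1.26) and miR-1274A (-1.18 ± 1.20), each with a limma adjusted p from 0.557 to 0.694. These 9 differences stayed below 0 under every alternative that tested them and without each sample, but their sizes moved. The smallest were -1.82 for miR-30c and -0.55 for miR-126 without post replicate 2, and -0.96 for miR-19b, -0.59 for miR-30a-5p, -0.54 for miR-1274B, -0.72 for miR-720 and -0.41 for miR-1274A without pre replicate 1. They were -0.34 for miR-323-3p and -0.12 for miR-597 with the 2 offset classes scaled separately, which also brought miR-106b to -1.62. After quantile normalization miR-1274B was at -4.50 and miR-30a-5p at -0.82. The -4.50 rests on pre replicate 1, where miR-520D-3P was at 0.64. There miR-1274B, at 4.75, was the highest always-detected assay and took the highest quantile. Its residual SD rose from 2.44 to 6.98. The same miR-520D-3P value also lowers the mean of the always-detected assays, and that of its offset class, in pre replicate 1.

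The differences of miR-222, miR-19b-1#, miR-203, miR-378 (listing 1), miR-875-5p, miR-378 (listing 2) and miR-146a lay between -1.15 and -0.76. The sign turned for miR-378 (both listings) and miR-146a without pre replicate 1, for miR-222 without post replicate 2 and for miR-146a without post replicate 4. Over the alternatives and without each sample, the differences ran from -1.56 to -0.08 for miR-19b-1#, -2.67 to -0.08 for miR-203 and -1.70 to -0.32 for miR-875-5p. miR-1305 was higher by 0.84 ± 0.95 (SE), by 0.53 without pre replicate 2 and by 1.49 with samples scaled to the mean of the always-detected assays. For miR-520D-3P, from the placental cluster, the post minus pre difference of 5.38 ± 3.83 (SE) came from pre replicate 1, with a log2 value of 0.64 against 20.45 to 21.47 in the other 3 pre samples. It was 0.31 without that sample. miR-24 differed by -0.41 ± 1.78 (SE), and it was higher in post samples under 4 other scalings and without post replicate 2. miR-520c-3p differed by 0.34 ± 1.21 (SE), by -0.70 without pre replicate 1 and by 1.73 after quantile normalization. miR-151-3p, not detected in pre replicate 1, differed by -0.02 ± 1.04 (SE), and by 0.45 when samples were scaled to the mean of the always-detected assays and 4.90 with undetected values set to the lowest value of the sample.

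A gain or loss of detection was the third comparison. miR-618 was detected in all 4 pre samples, at -2.46 ± 1.06 (SD, n = 4), and in none of the 4 post samples. This is the smallest p that Fisher's exact test allows here, 0.0286, and it was 1 after adjustment over 149 assays. The pre values of miR-618 reached down to -3.61, and its limit of detection in the post samples is not known. No assay was detected in all post samples and no pre sample. The following assays were singled out after their values were seen. miR-1183, miR-191 and miR-145, an miRNA abundant in smooth muscle, were detected in 3 of 4 pre and no post samples. miR-16 and miR-30b were detected in 4 of 4 pre and 1 of 4 post samples. In the other direction, miR-126#, the second strand of the endothelial miR-126 hairpin, was detected in 3 of 4 post samples at -4.08 ± 0.83 (SD, n = 3) and in no pre sample. The muscle miRNA miR-206 was detected in 3 of 4 post samples at -4.73 ± 0.35 (SD, n = 3) and in no pre sample. Each of these had a Fisher exact p of 0.143 and an adjusted p of 1. The lowest value of any assay was -2.42 in pre replicate 1 and -4.64 in pre replicate 4. It was -5.07 and -5.64 in pre replicates 2 and 3. All post values of miR-126# and miR-206 lay below the lowest value of pre replicate 1, so their absence there says little about a gain. The values of -4.99 for miR-126# and -4.96 and -4.90 for miR-206 also lay below the lowest of pre replicate 4. This reading takes 1 scale for all assays. Since the reference is not given, that is not known, and neither is the limit of detection of single assays. In a rank test with undetected values ranked lowest, miR-223, miR-16, miR-30b and miR-618 separated the groups completely (exact two-sided permutation p = 0.0286, the smallest possible), with an adjusted p of 0.307 over 43 assays.

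**Figure D3:**
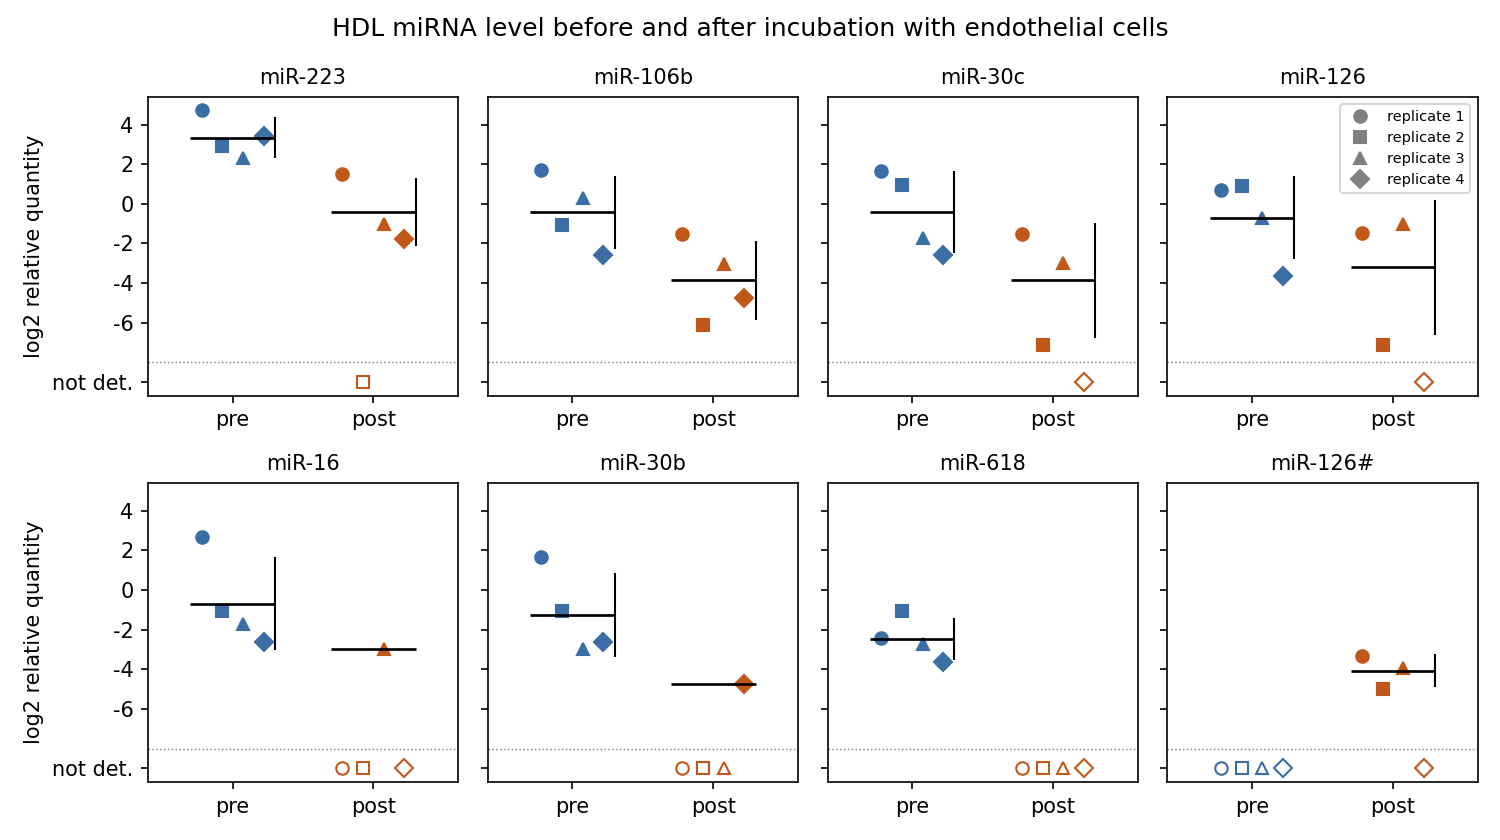
Log2 relative quantity (y axis) of 8 assays in 4 pre (blue) and 4 post (orange) samples, with 1 symbol per replicate number. Horizontal lines are means and vertical lines ± 1 SD over detected values, and open symbols below the dotted line are samples in which the assay was not detected. The detected values of miR-223 in post samples lie below all 4 pre values.

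The lists were compared by how many of their members were detected per sample. None of the 12 lists tested passed the threshold. The miR-30 family had the lowest p: 3.25 ± 0.50 of its members were detected in pre samples and 2.00 ± 0.00 in post samples (SD, n = 4; exact permutation p = 0.0286, adjusted 0.343). Its 2 tested members, miR-30c and miR-30a-5p, both had lower post means. Of the 8 let-7 assays, a family found in most tissues, 3 were detected, each in 1 pre sample, and none in post samples (exact permutation p = 0.143, adjusted 0.857). The miR-17 cluster and its paralogous clusters had 10 of 22 members detected. Of these, 9 were seen in pre replicate 1 and 8 in pre replicate 4, against 2 and 3 in the other pre samples and 3 to 6 in post samples (exact permutation p = 0.514). Their 3 tested members, miR-106b, miR-19b and miR-19b-1#, had lower post means and none passed (limma adjusted p over the list alone, lowest 0.0744).

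Endothelial miRNAs were detected at 2.50 ± 1.00 per pre and 3.75 ± 2.22 per post sample (SD, n = 4; exact permutation p = 0.543, adjusted 0.926). The list had 7 of 15 members detected. miR-126#, miR-100 and miR-193b were detected in 3, 2 and 1 of 4 post samples and in no pre sample (Fisher's exact p = 0.143, 0.429 and 1, adjusted p 1 for each), and post replicate 3 held all 7 of the detected members. Pre replicate 1 held no value of any assay as low as those of miR-126#. miR-126 and miR-222 were tested and did not pass. For leukocyte and platelet miRNAs the numbers were 3.00 ± 0.82 in pre and 2.75 ± 1.89 in post samples (exact permutation p = 1, n = 4 each), with miR-223 and miR-146a tested. Red-cell miRNAs were detected at 2.75 ± 2.36 in pre and 1.00 ± 0.00 in post samples (SD, n = 4; exact permutation p = 0.429). Pre replicate 1 held all 6 detected members, among them miR-451, miR-486-5p and miR-144#, which no other sample had. The placental cluster had 13 of 47 members detected, at 5.25 ± 1.26 per pre and 4.25 ± 1.5 per post sample (SD, n = 4; exact permutation p = 0.486), and its tested members miR-520D-3P and miR-520c-3p did not pass. Means for the imprinted cluster, with 11 of 60 members detected, were 2.75 ± 1.71 in pre and 2.75 ± 0.50 in post samples (exact permutation p = 1, n = 4 each), and miR-323-3p was its tested member. miRNAs measured earlier on HDL were detected at 5.25 ± 0.96 and 4.00 ± 1.41 (exact permutation p = 0.314), and regulators of endothelial inflammation at 4.00 ± 0.82 and 3.50 ± 1.29 (exact permutation p = 0.771). Heart and skeletal muscle (0.75 in pre and 1.25 in post, exact permutation p = 0.629) and epithelial miRNAs (1.5 in pre and 1.00 in post, exact permutation p = 0.714), which include miR-203, differed by less than the spread. Only 2 liver, 2 smooth-muscle and 1 neural assay were detected, which was too few to compare, and the control RNAs were not analysed here.

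The assays with the highest mean differed in how often they were detected. In post samples miR-520D-3P (mean log2 21.25) and miR-151-3p (17.21) were detected in all 4 samples and miR-573 (11.59) in 3. miR-29a (19.49), miR-628-5p (17.53), miR-518f (16.92), miR-25 (10.02), miR-20a and miR-302b were detected in 2 post samples each and miR-888 in 1. In pre samples the 10 highest included miR-520D-3P in 4 samples and miR-151-3p in 3, at means of 15.87 and 17.23. The other 8, miR-517a, miR-628-5p, miR-888, miR-523, miR-25, miR-150, miR-573 and miR-302b, were detected in 1 pre sample each. The same assay could take values far apart. miR-29a was at 18.82 and 20.17 in 2 post samples and between -4.59 and -2.04 in 3 pre samples, and miR-518f was at -2.80 and 18.40 in 2 pre samples.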

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

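The tests on the spread and on pre replicate 1 in this part were chosen after the results were seen; the counts over other splits were planned. Of 45 groups of 4 values checked for a value far from the rest, 4 were picked out, and chance picks about 1 in 20. All 4 concern pre replicate 1. Its mean rank correlation with the other pre samples, over the 16 always-detected assays, was 0.154, and the next lowest was 0.454. Its miR-520D-3P value was 0.64 on the log2 scale, where the nearest pre sample had 20.45. Its miR-19b-1# value was 0.67 against -3.02 for the nearest, and its miR-645 value was -0.26 against -3.51.

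The ranks of pre replicate 1 stood apart from all 7 other samples, with a mean Spearman correlation of 0.0924 across the 16 always-detected assays, which are not independent replicates, where the lowest of the others was 0.425. One scaling factor for the whole sample would leave these ranks as they are, so it cannot be a cause of the low correlation. Without miR-520D-3P the correlation was still 0.196 against 0.348 for the lowest of the others, so that assay is not the whole cause. Without both miR-520D-3P and miR-520c-3p it was 0.429, within the 0.294 to 0.606 of the others over the same 14 assays, but these 2 were the pair whose removal raised it most, and with each other sample freed of its own such pair the lowest was 0.604. Taking the 2 offset classes for the 2 cards, a separate scaling of each does not account for the low correlation alone: with each class centred on its median in each sample, it was 0.250 and the lowest of the others 0.583. A part of the cause in such a scaling stays open, since apart from those 2 assays the shifts against the other pre samples ran from -0.17 to 2.83 log2 units in 1 class and 1.12 to 4.49 in the other, and a different HDL preparation and sample handling were not tested.

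Pre replicate 1 also held all 6 red-cell miRNAs detected in the series, with miR-451 at a log2 value of 3.69 and miR-486-5p at 2.63. RNA from red blood cells in that sample is a candidate explanation, although the ultracentrifugation and anti-apolipoprotein A-I capture should remove cells. Over all 149 detected assays Fisher's exact test gave p = 0.00797 (two-sided; 0.0638 adjusted over the 8 samples), but miR-451, miR-486-5p and miR-144# are among those assays through this sample alone. Among the 130 assays detected in at least 1 other sample, 3 of 3 red-cell miRNAs were detected in pre replicate 1, where 1.13 would follow from its share (Fisher's exact test, two-sided, p = 0.0515), and other lists also hold miR-16 and miR-92a. This is the smallest p that 3 members allow here, so the test could not go below 0.05. With so few members the explanation stays open, and it leaves the low rank correlation open too, because none of the 16 always-detected assays is on the red-cell list.

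No assay passed the adjusted threshold although miR-223 was below every pre value wherever detected. Spacing at whole cycles, at 2.75% of the median residual variance, does not set the spread. The share of 1 sample in the spread stays open: without pre replicate 1 the median residual SD was 1.27 in place of 1.74 and that of 8 of 27 assays was lower by over 1.5 times, yet no assay passed (lowest limma adjusted p 0.400). Post replicate 2 was low in 1 offset class. Tested assays of that class detected in both differed from pre replicate 2 by -8.06 (miR-30c) to -5.05 (miR-106b). Those of the other class differed by -1.98 (miR-19b-1#) to 2.13 (miR-601). With the classes scaled separately, the residual SD of miR-222 went from 2.95 to 1.00 and that of miR-223 from 1.34 to 1.40. A shift of the whole class there cannot be told from changes in its assays. miR-223 is in this class. For the count of 0 passing assays the 35 splits of the samples into 4 and 4 decide nothing, since all 35 must reach it, and 9 of the 35 gave at least the real count of 2 at an unadjusted p under 0.05, so chance is not excluded for that count. The highest other split, with 4 passing assays and 9 at the unadjusted p, had post replicate 1 and pre replicate 4 exchanged and kept the other 3 pre and 3 post samples apart; whether the samples have a structure beyond their groups was not tested, and an effect of the incubation remains open.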

How the results depend on the processing

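The count of 0 passing assays held under scaling to the median or mean of the always-detected assays, quantile normalization, the stricter filter, undetected values at the lowest value, trend and robust options, removal of values over 1000, 2 separately scaled offset classes, the rank test, and without each sample in turn. Of these, the mean, lowest-value, over-1000, offset-class and rank settings were added after seeing the data. The replicate block gave 1 passing assay, miR-520D-3P, at 5.38 (limma adjusted p = 0.0221), which rests on pre replicate 1 and on a variance that the fit pooled over assays (SE 1.54, as for miR-106b, with residual SDs of 7.36 and 0.84), and 4 at an unadjusted p under 0.05. Same-numbered post values were lower in 4 of 4 pairs for miR-106b (limma adjusted p = 0.210 with the block) and in 3 of 3 for miR-223 (0.210). Titles of replicates 3 and 4 carry a further number, of unstated meaning, shared by pre and post. Deviations of same-numbered samples correlated at 0.07, -0.14, 0.09 and 0.63 over 16 assays, only replicate 4 correlating best with its own number. This cannot decide whether the numbers pair the samples, since miR-520D-3P alone had a pre SD of 10.16. The unpaired fit was planned as the main one, with the block as an alternative. Under the block the differences in detected assays (-10.5) and mean level (-0.65) did not pass (exact sign-flip p = 0.5 each, where 4 pairs cannot go below 0.125). The miR-223 difference kept its direction, from -5.45 to -3.14 over 7 other settings and from -4.73 to -3.10 without each sample, with limma adjusted p from 0.0849 to 0.605. The count of assays detected in all of one group and none of the other ran from 1 to 4 without 1 sample each (3 without pre replicate 3, 4 without post replicate 4), where groups of 3 make such a split easier. The sign turned for miR-24 under median (0.020), mean (0.24), quantile (1.38) and offset-class scaling (1.41), for miR-222 under quantile (0.26) and offset-class scaling (0.66) and for miR-378 (listing 2) under quantile normalization (0.082), and for miR-151-3p under median (0.017) and mean scaling (0.45) and with undetected values at the lowest value (4.90); the cause was not tested. Without 1 sample each, differences ran from -1.60 to 1.6 for miR-24, -2.45 to 0.11 for miR-222, -1.55 to 0.031 and -2.15 to 0.53 for miR-378 (listings 2 and 1), -2.06 to 0.75 for miR-146a, -0.70 to 0.87 for miR-520c-3p and -0.47 to 0.34 for miR-151-3p. Of the other recomputed values, 63 for the main comparisons and 334 for named assays stayed the same. For a difference this meant its direction and side of the threshold, and for a count an equal count. Several settings leave the difference of an always-detected assay as it was, so these totals do not measure how firm the results are. The depth behind each value is unknown. The planned Ct cutoffs, U6 reference, scaling by named card and set test were not run, as explained above.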

Other observations

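Some assays carry names that are not miRNA genes in the RefSeq table used. miR-720, miR-1274A and miR-1274B, whose sequences are known to derive from transfer RNA, have no miRNA gene of that name there, but were detected in all 8 samples. Their log2 levels were 1.64 ± 2.29, 0.39 ± 2.06 and 1.38 ± 3.20 in pre and 0.21 ± 0.88, -0.79 ± 0.88 and -0.28 ± 1.28 in post samples (SD, n = 4 each), and none passed the threshold. The name miR-886 belongs there to a vault RNA gene, VTRNA2-1. Of its 2 assays, miR-886-5p was detected in 2 post samples and miR-886-3p in 1, and neither in a pre sample (Fisher's exact p = 0.429 for miR-886-5p).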
